A study of Mus musculus with 55 samples.

How the data were processed

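Single-cell RNA was measured by mCEL-Seq2, a plate-based 3' tag method with molecular identifiers (UMIs), in CD45+ cells sorted from mice with experimental autoimmune encephalomyelitis (EAE, an immunisation model of multiple sclerosis) and from naive mice. The deposit holds 55 libraries of 192 wells each, 10560 wells in all. Per the labels, cells came from the leptomeninges (Men), from perivascular space and parenchyma together (PV), from choroid plexus (CP) or from blood monocytes, at the naive stage, at preclinical days 4 and 8, at onset and at peak of disease, and the sort left out cells positive for Ly6G, CD3e, CD19 or NK1.1. The series gives 16 to 18 C57BL/6N mice aged 8 to 10 weeks from 3 experiments and 384-well plates, but no label ties a library to a mouse, an experiment or a plate. Libraries were therefore taken as the unit of replication, and no test of a stage or compartment counted cells as replicates. Libraries of a group may still come from the same mice, so the p values, SEs and SDs may not measure the spread between mice. No paired analysis by mouse was possible because the labels do not say which libraries share one. Age followed the stage, with 8 weeks in naive mice, 9 at days 4 and 8 and at onset, and 10 at peak. Age and stage can therefore not be told apart in the comparisons with naive mice.

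The deposited values are expected counts: the authors turned the observed UMIs of each gene and cell into estimated transcripts by a correction for UMI collisions, without scaling for depth. All nonzero values (100 percent) gave a whole UMI count when that correction was inverted, and there were 0 missing or negative values. The labels name bcl2fastq 2.17.1.14 and BWA 0.6.2-r126. The genome build, the gene annotation and the counting program are not given in the sources used here, so genes are named by the symbols in the files, without positions. Library totals ran from 145770 to 1507020 transcripts. Features named Gm followed by digits (24.3% of all transcripts, of which Gm10800 alone held 17.6%), mitochondrial features (7.95%) and spike-in RNA (0.085%) were left out, which kept 20695 features.

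Wells with at least 1000 remaining transcripts were kept, 3971 in all, and 50 of them were removed because Kcnq1ot1 held more than 2% of their transcripts, a usual sign of a low-quality cell in this protocol. The 3921 cells kept (37.1% of wells) had a median of 4250 transcripts. They were scaled to 10000 transcripts, log-transformed, reduced to 30 principal components of the 2000 most variable genes and clustered by the Leiden method at resolution 1 on 15 nearest neighbours (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). Clusters were named from 21 marker lists written before the data were examined, when at least 3 markers of a list were raised 1.5-fold or more and their mean z score was at least 0.5, unless the 10 leading genes of a cluster held more markers of another class. Of the 24 clusters, 22 received a name. Names end in "-like" because they rest on transcripts alone. Classical-monocyte-like and monocyte-derived-like clusters were joined as the monocyte lineage.

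Some of these settings were chosen after the clusters had been seen, but before any comparison of groups. The first naming definition asked leading genes for 25% of cells and a pseudocount of 0.1, in place of 50% and 1, and asked for a mean z score of 1 and a marker fold of 2. Under it, clusters 4 and 10 were left without a class. Resolutions of 0.3 and 0.5 were also looked at. The exclusion of Gm, mitochondrial and spike-in features and the Kcnq1ot1 limit were set after seeing the files as well. Class sums with the first leading-gene definition and with Gm features are among the alternatives.

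For each library and class with at least 10 cells, transcripts were summed over cells and rounded to whole numbers. Sums were compared in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM normalisation and its filter on low counts. Each fit held all libraries of the class in its compartment, or in both compartments compared, with groups as the only term. The comparison of 2 classes within PV carried the library as a block. P values were adjusted by Benjamini and Hochberg over all genes of a comparison, with 0.05 as the threshold. Errors of log2 changes are standard errors derived from the test statistic. Levels are in CPM, the edgeR unit for counts scaled to a common effective library size, with the SD between libraries. A group with 1 library was assumed to vary like the other groups of its fit. In the fit for leptomeningeal border macrophages, 1 residual degree of freedom was left. Against an arm at 0 counts, the fold is a lower bound from a floor of 3 counts over the arm's libraries. Intervals and floors cover counting error only.

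Genes were named by a rule set before the data were examined: among genes past the threshold with at least a 2-fold change and an average log2 CPM of 5 or more, the 10 with the largest rise and the 10 with the largest fall for which every library of the first arm lay on that side of the mean of the second. Up to 4 past members of each response list were added. Gm and Rik names, mitochondrial genes and ribosomal protein genes were counted but not named. The 14 response lists were fixed beforehand and tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Members past the threshold are given over all genes tested and, in those words, adjusted over the list alone.

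Class shares were compared between each later stage and naive with two-sided exact permutation tests over libraries, with adjustment over all 120 tests. Blood had 1 library per stage, so it was described with exact binomial (Clopper-Pearson) and exact Poisson 95% intervals and without a test. For each library, the class make-up of 3 blocks of 64 consecutive wells was compared by permutation. A recovery check on simulated counts changed 100 genes 2-fold and 100 genes 8-fold in each design. For 6 onset against 3 naive PV libraries, edgeR recovered 13 and 87 of them with 4 false calls. For the border macrophage designs against naive, at most 7 of the 2-fold genes and between 50 and 76 of the 8-fold genes were recovered.

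The alternatives set before the data were examined were DESeq2 1.42.0, relative log expression factors, no filter on low counts, cell filters of 500 and 2000 transcripts, clusters built without response genes, a doubled clustering resolution, a minimum of 20 cells, removal of the 2% of cells with most transcripts, libraries with a shared title prefix summed, libraries titled C or EAE left out, only the 2 groups compared, a block, and each library left out in turn. Alternatives chosen after seeing the data were Gm features kept, molecule counts before the collision correction, a minimum of 5 cells, the first naming definition, libraries standing apart left out, the spike-in batch as a covariate, only libraries that list spike-in features, and all CNS libraries with compartment as a covariate. The 16 libraries without listed spike-in features were nearly all naive or day 4 libraries, which makes the listing a marker of batch. The rise and fall of leptomeningeal border macrophages at day 8 could not be fitted, because no library of that group held 10 such cells.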

Results

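The data comprised 55 libraries of sorted CD45+ cells from mice with EAE and from naive mice. PV was sampled with 4 naive, 2 day 4, 4 day 8, 6 onset and 4 peak libraries. Men was sampled with 3 naive, 2 day 4, 3 day 8, 7 onset and 3 peak libraries, and CP with 2, 2, 3, 3 and 4. Blood had 1 library each at naive, day 4 and onset. Library totals ran from 145770 to 1507020 transcripts, and 7 to 164 cells per library passed the filters. The lowest library median was 1736 transcripts per kept cell, and the median over all kept cells was 4250.

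Of the 3921 cells, 1194 (30.5%) were microglia-like in 5 clusters, led by P2ry12, Gpr34, Siglech, Tmem119 and Hexb in the largest. Border-macrophage-like cells numbered 930 (23.7%), in 3 clusters with Mrc1, Apoe, Stab1, Cd163, Pf4 and Ms4a7 among their leading genes. The monocyte lineage held 672 cells (17.1%), with Ly6c2, Plac8, Chil3 and Ccr2 leading its classical clusters and Arg1, Fn1 and Tgm2 its monocyte-derived cluster. Smaller classes were neutrophil-like (276 cells), T cell-like (235), nonclassical-monocyte-like (220), cDC2-like (147), migratory-DC-like (68), NK- or ILC-like (41), fibroblast-like (22), mast-cell- or basophil-like (12) and choroid-plexus-epithelium-like (9). A further 95 cells in 2 clusters stayed unnamed. The make-up of 15 of the 52 CNS libraries stood apart from the others with their compartment label, 4 in PV, 7 in Men and 4 in CP.

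**Figure D1:**
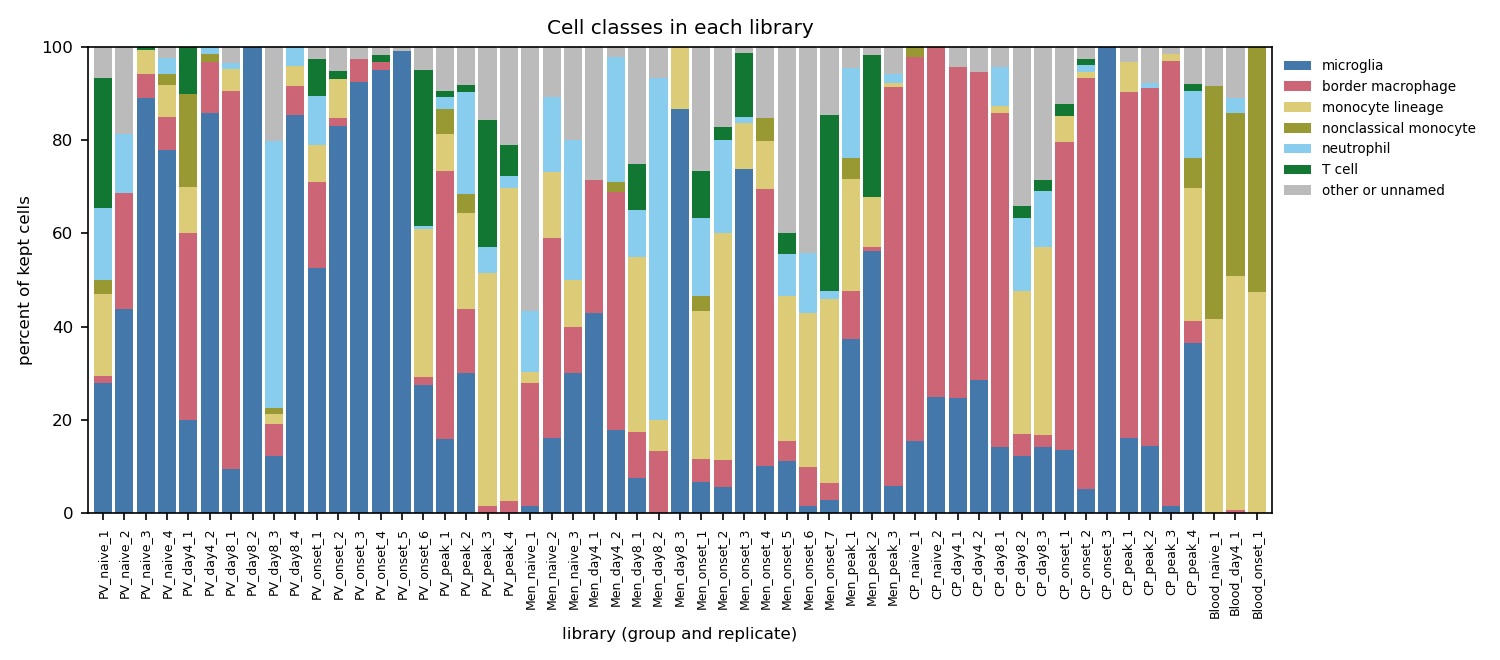
Percent of kept cells in each class (stacked bars, vertical axis in percent) for each of the 55 libraries (horizontal axis), ordered by compartment and stage. Border-macrophage-like cells made up 81.2% of PV_day8_1 and at most 6.74% of the other day 8 PV libraries, and microglia-like cells made up 73.8% of Men_onset_3 and at most 11.1% of the other onset Men libraries.

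The first question was how the resident microglia-like cells of PV changed along the disease. Before clinical signs, no gene passed the threshold of edgeR at day 4 (1 against 3 libraries) or at day 8 (3 against 3), of 6511 genes tested. At an unadjusted p under 0.05 there were 159 genes at day 8 and fewer at day 4, and DESeq2 called 1 gene at day 4 and 0 at day 8. Interferon-inducible, MHC and homeostatic lists held no member past the threshold at either stage. At day 8 the type I interferon list was higher by camera (median log2 change 0.39, adjusted p 0.000872, but 0.751 with an estimated correlation). By camera the inflammatory monocyte-derived list was lower (-2, 1.54e-07 and 0.746), as were the disease-associated microglia and stress lists. At day 4 the type I interferon and inflammatory monocyte-derived lists had medians of -0.538 and -2.64. The 30 tested members of the proliferation list, genes of DNA replication and mitosis, had a median log2 change of 1.84 at day 4, with an adjusted camera p of 3.49e-23 that became 0.294 with an estimated correlation. The single day 4 library gives that value no spread of its own. In simulated data of this design, 58 and 75 of 100 genes changed 8-fold were recovered, and 2 and 7 of 100 genes changed 2-fold.

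At onset, microglia-like cells of PV carried a broad interferon response together with lower homeostatic transcripts. The median mitochondrial share of kept cells was also higher in the onset libraries, 8.33 to 18.3% against 4.06 to 6.82% in naive PV. The class also sat in other clusters at the 2 stages: clusters 2 and 9 held 72.6 and 21.8% of naive PV microglia-like cells and 2.2 and 0.31% at onset, and clusters 4, 11 and 12 held 50.6, 25.5 and 21.4% at onset. The guanylate-binding protein gene Gbp2, induced by interferon gamma, rose from 28.6 ± 34.9 CPM (SD, n = 3) to 966 ± 279 CPM (n = 6), a log2 change of 5.44 ± 0.54 (SE, edgeR adjusted p 2.95e-06). Cxcl9, a chemokine that attracts T cells, was at 0 in all 3 naive libraries and at 259 ± 197 CPM at onset, at least 63-fold higher. Gpr34 and P2ry12, receptors typical of resting microglia, fell by 2.47 ± 0.32 and 1.77 ± 0.32 on the log2 scale. P2ry12 stood at 887 ± 133 CPM at onset and at 3006 ± 1075 CPM in naive mice. In all, 432 genes rose and 469 fell of 6511 tested, and each gene named had all 6 onset libraries on one side of the naive mean except H2-DMa.

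**Figure D2:**
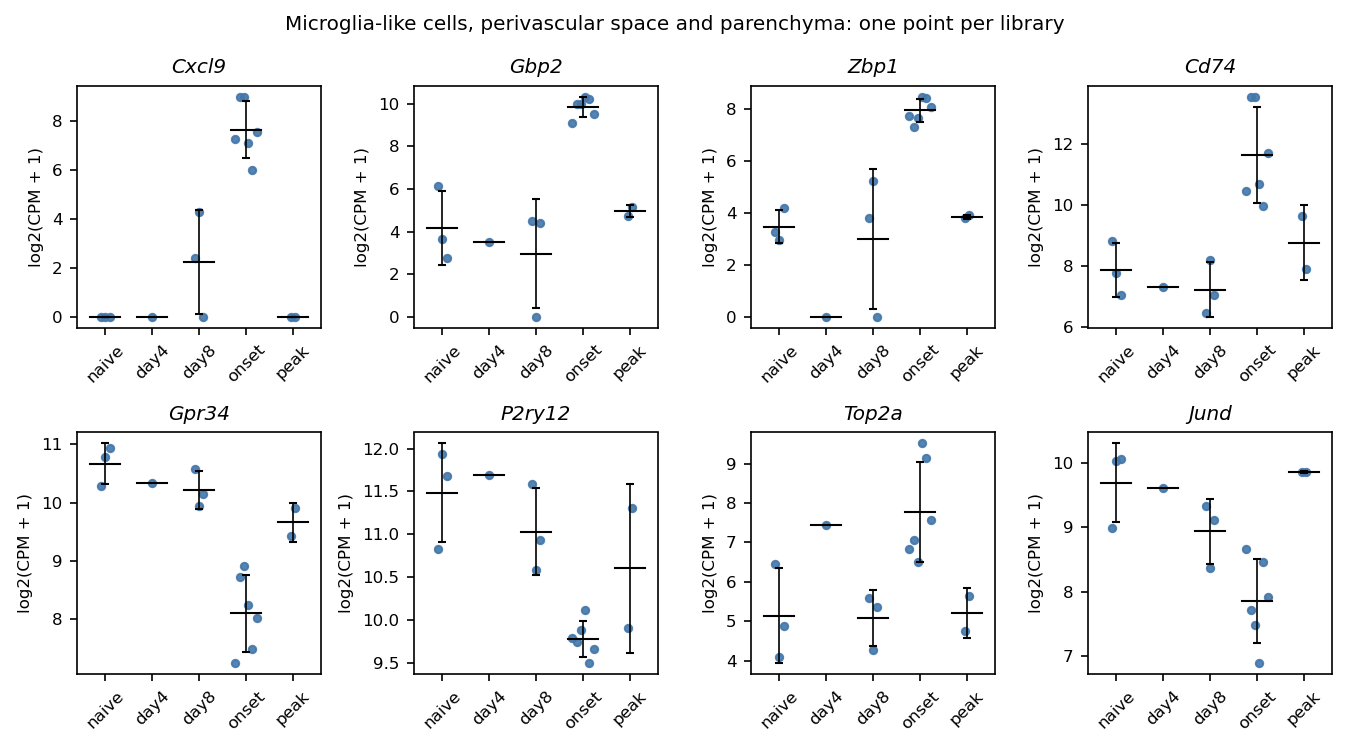
Level of 8 genes in microglia-like cells of PV as log2(CPM + 1) (vertical axes) at the 5 stages (horizontal axes). Points are libraries, lines are means and bars are SD where a stage has more than 1 library; Gbp2 lies between 543 and 1284 CPM in the 6 onset libraries and reaches 68.8 CPM in the highest naive one.

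Of 17 tested interferon gamma genes, 13 rose and 0 fell, and adjusted over the list alone the count was also 13. Besides Gbp2 and Cxcl9 they included Gbp4 (5.61 ± 0.76), Iigp1 (5.47 ± 0.67), an immunity-related GTPase, and the Fc receptor gene Fcgr4 (3.60 ± 0.36), all as log2 changes. Of 25 type I interferon genes, 17 rose (21 adjusted over the list alone), among them the nucleic acid sensor Zbp1 (4.66 ± 0.51), Oasl2 (2.96 ± 0.46), Ifi204 (2.81 ± 0.41) and Rtp4 (2.55 ± 0.39). Of 14 MHC class I genes, 10 rose (13 adjusted over the list alone). They included the peptide transporter Tap1 (2.24 ± 0.36), the immunoproteasome subunit Psmb8 (1.65 ± 0.31), its activator Psme1 (1.83 ± 0.27) and H2-Q6 (2.46 ± 0.43), whose reads may be shared with other H2-Q genes. Of 13 MHC class II genes, 3 rose (7 adjusted over the list alone): Cd74, the invariant chain, with 4.32 ± 0.82, Ifi30 with 1.89 ± 0.30 and H2-DMa with 1.09 ± 0.35. Of 25 homeostatic genes, 16 fell and 0 rose (19 fell adjusted over the list alone), among them Cst3 (-1.77 ± 0.30) and the fructose transporter Slc2a5 (-1.88 ± 0.35). Gpr34, P2ry12 and Cst3 were also leading genes of 1 of the 5 microglia clusters. The interferon gamma, type I interferon, MHC class I and homeostatic lists kept an adjusted camera p under the threshold with an estimated correlation (0.00822, 0.0313, 0.0259 and 0.0313), and the MHC class II list had 0.223.

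**Figure D3:**
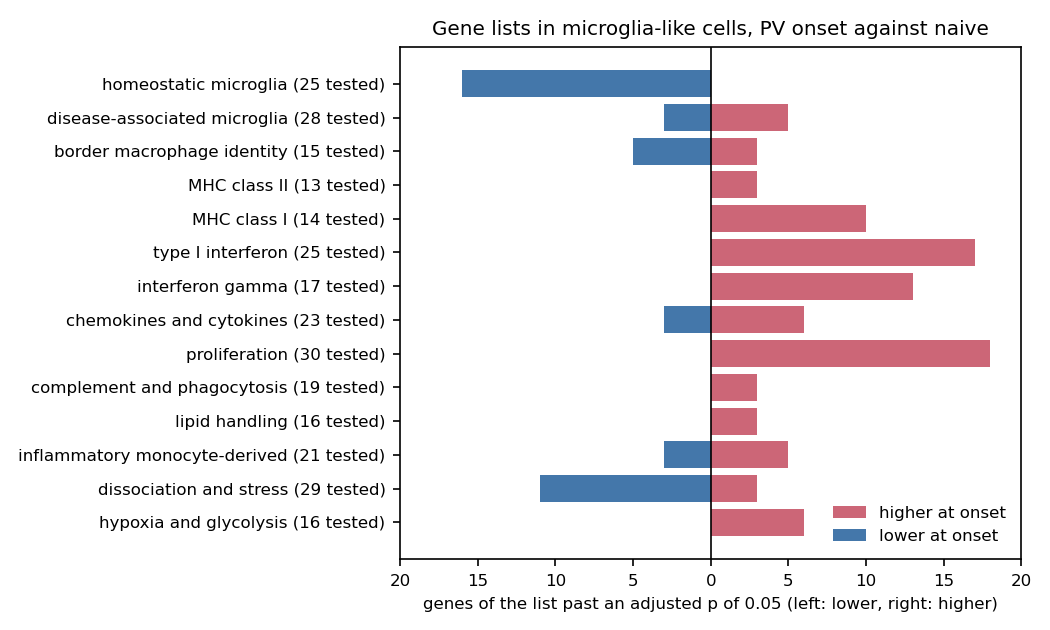
Number of members of each of the 14 gene lists past the threshold in microglia-like cells of PV at onset against naive (horizontal axis: genes, lower to the left and higher to the right; number tested beside each list name). The largest counts are 18 of 30 proliferation genes and 17 of 25 type I interferon genes higher, and 16 of 25 homeostatic genes lower.

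Cell cycle genes rose too: 18 of 30 proliferation genes passed (26 adjusted over the list alone), among them Top2a (3.15 ± 0.69) and Cenpa (2.94 ± 0.67), with Top2a the leading gene of cluster 12, which held 3 of 234 naive and 68 of 318 onset cells of the class. Among chemokines and cytokines, 6 of 23 rose and 3 fell, with higher Ccl2 (3.64 ± 0.51), Ccl12 (3.55 ± 0.44) and Ccl7 (4.76 ± 1.04), which attract monocytes, and lower Ccl9 (-1.68 ± 0.32). Ccl2 and Ccl12 were leading genes of a microglia cluster. Other large rises were the complement gene C4a (6.22 ± 0.77), the adenosine receptor gene Adora1 (6.06 ± 0.71), Irg1 (4.69 ± 1.05), which makes itaconate, and the lipid receptor genes Cd300lf (5.23 ± 0.71), Cd36 (4.03 ± 0.74) and Msr1 (3.46 ± 0.68). Of 19 complement and phagocytosis genes 3 rose, as did 3 of 16 lipid handling genes. Hypoxia and glycolysis genes had 6 of 16 higher, including Pkm (1.54 ± 0.31) and Ldha (1.42 ± 0.29). Of 28 disease-associated microglia genes 5 rose, such as Cd52 (1.81 ± 0.41), and 3 fell, including Lpl (-2.09 ± 0.42, but 0.049 with only the libraries that list spike-in features), and camera gave 0.0635. The dissociation and stress list had 11 of 29 members lower, with Jund (-1.82 ± 0.33), Dusp1 (-2.25 ± 0.44) and Fos (-2.45 ± 0.52), and 3 higher. Cluster 9, led by Egr1 and Jun, held 51 naive cells and 1 onset cell of the class. With an estimated correlation, the proliferation, chemokine, complement, lipid, glycolysis and stress lists each had an adjusted p of 0.223.

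Genes with the largest falls at onset included Mmp12, macrophage elastase (-6.73 ± 1.08), the sialyltransferase genes St8sia6 (-4.46 ± 0.54) and St8sia4 (-3.43 ± 0.60), Mgll, which hydrolyses endocannabinoids (-3.63 ± 0.46), and Sox4 (-3.23 ± 0.48). Mmp12 was uneven in naive mice, at 0, 52.3 and 304 CPM in the 3 libraries. Markers of other cells also fell: Hba-a1 and Hbb-bs of erythrocytes (-8.04 ± 1.45 and -6.24 ± 1.32), Ngp and Ltf of neutrophils (-4.11 ± 0.98 and -4.09 ± 1.34), Ly6c2 and Chil3 of classical monocytes (-2.72 ± 0.81 and -3.51 ± 1.10) and Cbr2 of border macrophages (-4.06 ± 0.73). Hba-a1 was at 602, 2.27 and 779 CPM in the naive libraries. Of 15 border macrophage identity genes 3 rose and 5 fell, and of 21 inflammatory monocyte-derived genes 5 rose, such as Ly6a (3.89 ± 0.53), and 3 fell.

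The count of 901 genes at onset depended on the naive libraries: it was 536, 343 and 430 without PV_naive_1, PV_naive_3 and PV_naive_4, and 489 without the libraries titled C or EAE. PV_naive_1 was the one naive library of the same spike-in batch as all onset libraries, and with the batch as a covariate 127 genes passed. For the 901 genes the median size of the log2 change was 1.57 without and 1.55 with the covariate, with 898 in the same direction, while the median SE went from 0.402 to 0.564. Within the batch (6 against 1 library) 8 genes passed, and 250 passed when all CNS libraries were fitted with compartment as a covariate (244 shared).

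At peak, microglia-like cells of 2 PV libraries were compared with the same 3 naive libraries, on 12 to 22 cells each. PV_peak_1 stood apart from the other PV libraries, with a make-up and a well pattern like those of CP. H2-Q4, a nonclassical MHC class I gene of a family with similar sequences, was the 1 gene past the threshold. It rose by 4.24 ± 0.58 on the log2 scale (edgeR adjusted p 0.00125), from 21.3 ± 6.35 CPM (SD, n = 3) to 396 ± 193.4 CPM (n = 2), and stood at 22.5 ± 18.6 CPM at onset (n = 6). At an unadjusted p under 0.05 there were 405 genes, and H2-Q4 stayed past the threshold without PV_peak_1 while its call was lost without PV_peak_2, without PV_naive_3 or with the spike-in batch as a covariate.

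The second question was how border macrophages responded in CP and Men. In border-macrophage-like cells of CP at day 4, Ccl7 and Ccl12 were the 2 of 20 members of the chemokine and cytokine list that rose (camera adjusted p 0.00364, but 0.458 with an estimated correlation). The dissociation and stress list was also higher, with 1 of 29 members past and 8 adjusted over the list alone (camera adjusted p 4.12e-11, but 0.271 with an estimated correlation). Ccl8, of the border macrophage identity list, went from 19.7 ± 8.98 CPM in naive mice (SD, n = 2) to 293 ± 143 CPM at day 4 (n = 2), with log2 changes of 3.75 ± 0.73 at day 4, 4.16 ± 0.75 at day 8, 3.36 ± 0.73 at onset and 4.58 ± 0.66 at peak. Ccl7 rose by 3.45 ± 0.63 at day 4 and 3.76 ± 0.66 at day 8, and Ccl12 by 2.29 ± 0.44 and the chemokine receptor gene Ccr1 by 1.99 ± 0.40 at day 4. Fosb, an immediate early gene, rose by 2.50 ± 0.49 at day 4 and was a leading gene of 1 of the 3 border macrophage clusters. Under the first naming definition, which drops that cluster, it had -0.37. Slc13a3, Caps2, Usp29 and Nkain3 fell at day 4, by 3.81 ± 0.78, 3.13 ± 0.58, 2.78 ± 0.60 and 2.18 ± 0.40. Day 8 rested on 1 library and added C4a (2.64 ± 0.54), the metallothionein gene Mt1 (2.03 ± 0.49), Il4ra (2.09 ± 0.49) and the interferon-induced Oasl2 (1.96 ± 0.48).

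**Figure D4:**
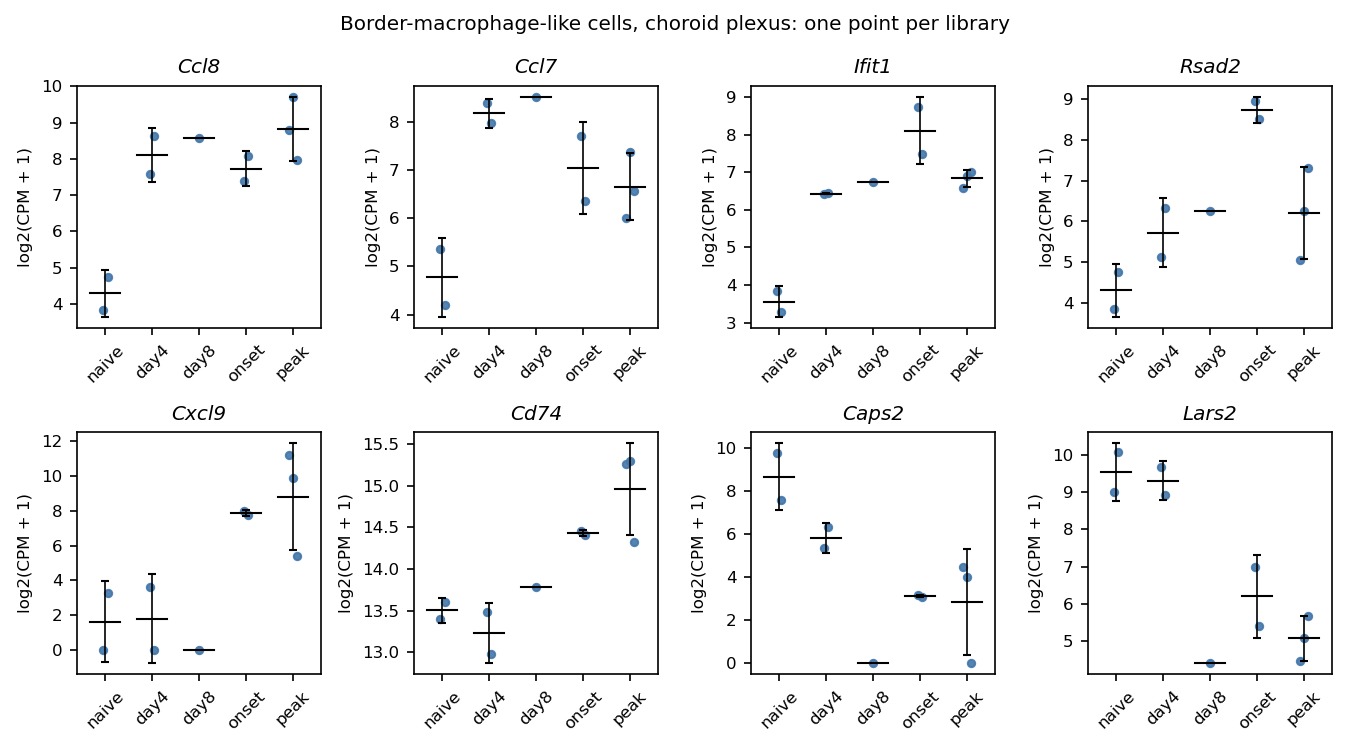
Level of 8 genes in border-macrophage-like cells of CP as log2(CPM + 1) (vertical axes) at the 5 stages (horizontal axes). Points are libraries, lines are means and bars are SD where a stage has more than 1 library; Ccl8 lies at 13.4 and 26.1 CPM in the naive libraries and between 166 and 835 CPM in all later ones, and Lars2 falls from 792 CPM in naive mice to 34.9 CPM at peak.

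At onset the interferon-induced antiviral genes Ifit2, Ifit1 and Rsad2 rose in CP border-macrophage-like cells, by 5.22 ± 0.85, 4.74 ± 0.69 and 4.32 ± 0.62. Rsad2 was at 430 ± 96.1 CPM at onset (n = 2) and at 19.7 ± 8.98 CPM in naive mice (n = 2). Of 28 type I interferon genes 11 rose at onset (20 adjusted over the list alone) and 4 at peak (7), and of 16 interferon gamma genes 7 rose at onset (13) and 4 at peak (7, with 1 lower), among them Stat1 with 1.72 ± 0.35 and 1.54 ± 0.33. Gbp4, at 0 in the naive libraries, was at least 5.8-fold higher at onset and at least 4.07-fold higher at peak. At peak, Cxcl9 rose by 7.50 ± 1.35, Cxcl10 by 4.30 ± 1.01, the complement gene C3 by 5.34 (adjusted p 0.00592) and Ly6a by 3.77 ± 0.50. The 3 peak libraries were uneven, with Cxcl9 at 2346, 935 and 40.8 CPM, C3 at 1136, 306 and 69.1 CPM and Cxcl10 at 170, 430 and 37.7 CPM. The calls of C3 and Cxcl10 were lost without either naive library, and that of Cxcl10 also without CP_peak_2. Antigen presentation genes rose at peak, with 3 of 11 MHC class II genes (7 adjusted over the list alone): Cd74 by 1.51 ± 0.28, H2-Ab1 by 1.23 ± 0.26 and Ifi30 by 1.85 ± 0.40. Cd74 and H2-Ab1 led the cluster that held 0% of naive and 69.4% of peak border-macrophage-like cells of CP. With an estimated correlation no list stayed past the threshold in CP: the type I interferon list had adjusted p values of 0.147 and 0.284 at onset and peak, the interferon gamma list 0.135 and 0.182, and the MHC class II list 0.162 and 0.0771.

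The falls in CP at onset and peak were shared in part, with 53 genes lower at both stages. Among them were Caps2 (-5.96 ± 0.70 at onset and -5.65 ± 0.63 at peak), Usp29 (-4.57 ± 0.64 and -6.19 ± 0.70) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (-3.33 ± 0.43 and -4.37 ± 0.42). Caps2 and Usp29 were uneven in naive mice, at 868 and 191 CPM and at 1001 and 113 CPM in the 2 libraries, and without CP_naive_1 Usp29 had -2.28 at onset (adjusted p 0.207). Ndrg1 also passed at both stages, but was at 507 CPM in CP_naive_1 and 8.69 CPM in CP_naive_2. Caps2 was at 0 in the day 8 library, at least 52-fold lower than in naive mice. Between spike-in batches of PV microglia-like cells before onset, Lars2 also differed by -3.65 and Mid1 by -2.64 on the log2 scale. The chemokine genes Cxcl1 and Cxcl2 and the cytokine gene Tnf fell at peak (-7.16 ± 1.44, -2.16 ± 0.47 and -2.65 ± 0.72). These 3 and Acp5 took the other sign without CP_naive_1 (1.82, 0.40, 0.35 and 1.09).

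By edgeR, 5 genes rose and 6 fell in CP at day 4, 8 and 38 at day 8 (1 against 2 libraries), 59 and 69 at onset (2 against 2) and 34 and 87 at peak (3 against 2), of 6184 tested. Both naive CP libraries and both day 4 libraries were of the batch without listed spike-in features and all later ones of the other, so batch and stage cannot be told apart from day 8 on. Without CP_naive_1 the counts were 3, 15, 59 and 44. They were 3 and 4 at day 4 without CP_day4_1 and CP_day4_2, 63 and 76 at onset without CP_onset_2 and CP_onset_1, and DESeq2 gave 29, 69 and 78 from day 8 on.

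In Men, the only onset and peak libraries with enough border-macrophage-like cells were Men_onset_4 and Men_peak_3. Both stood apart from the other Men libraries, with a make-up and a well pattern like those of CP. Each stage was 1 library and the residual spread came from the 2 naive libraries, so the errors and calls carry no spread between libraries of onset or peak, and the values are differences of these libraries from naive rather than responses of a stage. In them, Ttr, a choroid plexus epithelium marker, was at least 19.6-fold and at least 8.13-fold higher than in the 2 naive Men libraries, where it was at 0. Lyve1, a marker of leptomeningeal and perivascular macrophages, was lower, at -5.17 ± 0.70 and -7.51 ± 0.86. The interferon-induced Ifit1 was higher by 4.16 ± 0.79 and 4.01 ± 0.79, Rsad2 by 3.45 ± 0.82 and 4.18 ± 0.78, and Ly6a by 4.89 ± 0.85 and 5.71 ± 0.82. Of the neutrophil markers, in Men_onset_4, S100a9 was at least 69.4-fold and Lcn2 at least 35.1-fold lower. Of 29 stress genes, 20 were lower in Men_onset_4 and 21 in Men_peak_3 (24 at each adjusted over the list alone), including Jun (-3.24 ± 0.45 and -3.45 ± 0.45) and Egr1 (-3.13 ± 0.46 and -3.76 ± 0.48). With an estimated correlation the stress list had adjusted p values of 0.458 and 0.308. Of 28 type I interferon genes 9 and 7 were higher (21 and 17 adjusted over the list alone), with 0.458 and 0.308 as well.

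In all, 30 genes were higher and 97 lower in Men_onset_4, and 144 differed in Men_peak_3 with 38 of them higher, of 4013 tested by edgeR on 1 against 2 libraries with 1 residual degree of freedom. DESeq2 called 31 and 34 genes, all lower, and with cells of at least 500 transcripts no gene passed at either stage. In Men_day4_2, the only day 4 library with enough such cells, Cd300ld was higher by 2.45 ± 0.64 and 10 genes were lower, among them Lyve1 (-2.78 ± 0.66), the folate receptor gene Folr2 (-4.63 ± 1.07) and the classical monocyte markers Ly6c2 (-3.72 ± 0.94) and Chil3 (at least 8.57-fold lower), but DESeq2 called 0. Day 8 could not be fitted at the minimum of 10 cells.

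The third question was how border macrophages differ between Men and CP. Over the 4 stages with libraries in both (5 Men and 9 CP libraries), Lyve1 was higher in Men by 4.71 ± 0.77 on the log2 scale (edgeR adjusted p 0.000944), with 1032 ± 305 CPM in naive Men (SD, n = 2) and 0 in naive CP (n = 2), and with 5.05 CPM in Men_peak_3. The monocyte chemoattractant gene Ccl2 was higher in Men by 1.93 ± 0.40. Immediate early and stress genes were higher in Men, 17 of 29 of their list (23 adjusted over the list alone), with Fos by 1.33 ± 0.16, Jun by 1.45 ± 0.20, Egr1 by 1.86 ± 0.26 and Klf4 by 1.65 ± 0.25. Among the 9 genes lower in Men was Ly6a (-2.95 ± 0.63), though not in every Men library. MHC class II genes were lower in Men as a list, with 0 of 11 past over all genes and 8 adjusted over the list alone. The stress and MHC class II lists stayed past the threshold with an estimated correlation (adjusted p 0.00502 and 0.0378).

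Men was higher for 34 genes and lower for 9 of 6330. A cluster led by Fos, Egr1 and Cxcl2 held 75.4% of naive border-macrophage-like cells in Men and 5.48% in CP. The first naming definition left that cluster without a class and kept 2 Men libraries, Men_onset_4 and Men_peak_3, and 5 CP libraries. Then 7 genes passed with none higher in Men, and Klf4, Fos and Cxcl2 turned to -0.36, -0.19 and -0.17. Such a fit removes cells by the genes compared and leaves the 2 Men libraries that stood apart, so it does not show where the stress difference lies. Without the libraries standing apart 98 genes passed (86 higher in Men), without Men_peak_3 there were 66, without Men_day4_2 there were 23, without CP_onset_2 there were 26, and within the spike-in batch 8. A fit with the title number as a block gave no value.

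The Men side of the next comparison was 1 library at each stage, Men_onset_4 or Men_peak_3, with no spread of its own. Both stood apart, with a make-up like that of CP, so a difference of responses cannot be told apart from a wrong compartment label. The change from naive differed between it and CP for 51 genes at onset and 14 at peak. At onset the signed change was more positive in Men for 9 genes, among them the epithelium marker Ttr (by 10.2 ± 2.32), H2-Q4 (4.55 ± 0.87), Cd4 (3.54 ± 0.84) and Gpr34 (2.67 ± 0.67). It was more negative for 42, such as the stress genes Socs3 (-5.28 ± 0.75), Dusp1 (-4.47 ± 0.67) and Fos (-3.59 ± 0.47). Dusp1 and Fos were lower in Men_onset_4 (-2.61 ± 0.46 and -1.76 ± 0.39) and rose in CP (1.86 ± 0.42 and 1.83 ± 0.29). At peak the signed change was more positive for Fgl2 (3.06 ± 0.64) and more negative for 13 genes, including Lyve1 (-10.55 ± 2.28), Lgals3 (-5.28 ± 1.07), Osm (-4.89 ± 0.98) and Klf4 (-3.65 ± 0.70). Stress genes had a more negative change in Men as a list, 16 of 29 at onset and 7 at peak (24 at each adjusted over the list alone), with adjusted p values of 0.0116 and 0.0061 with an estimated correlation. Without CP_naive_2 the counts of genes that differed were 29 and 1. Without CP_onset_1, CP_onset_2 and Men_naive_1 the onset count was 22, 16 and 27. Without CP_naive_1, CP_peak_2 and CP_peak_3 the peak count was 29, 8 and 41. Between microglia-like cells of PV and border-macrophage-like cells of Men, the signed change from naive to peak was more positive in the former for H2-Q4 (6.04 ± 1.08) and the stress-induced Csrnp1 (4.54 ± 0.82), 2 of 6403 genes. The count was 4 without PV_peak_1, 1 without PV_peak_2, PV_naive_3 or Men_naive_1, and 0 without PV_naive_1, PV_naive_4 or Men_naive_2.

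The fourth question was what sets the cells of the monocyte lineage apart from resident cells in the same tissue. In PV_onset_6 and PV_peak_2, the libraries with enough cells of both classes, the aspartic protease gene Napsa was at least 55.4-fold higher in monocyte-lineage-like than in microglia-like cells. The antiprotease gene Slpi was at least 27.2-fold higher and the lipid-hydrolysing Pla2g7 higher by 7.72 ± 1.13 on the log2 scale. In microglia-like cells, Hpgd, which degrades prostaglandins, was at least 26.4-fold and Npnt at least 26.9-fold higher, and Adamts1, Sall3 and Cd34 were higher by 7.52 ± 1.04, 6.12 ± 0.92 and 5.81 ± 0.87. Of 25 inflammatory monocyte-derived genes 21 were higher in the monocyte lineage (23 adjusted over the list alone), with Sirpb1c by 6.45 ± 0.94, Plac8 by 5.96 ± 0.95 and Ccr2 by 5.56 ± 0.92. Of 23 homeostatic genes 19 were lower (22), with Sall1 at least 39-fold and Fcrls by 5.30 ± 0.87. Plac8, Ccr2, Sall1 and Fcrls are class markers, so their direction follows from how the classes were named. Vegfa (4.47 ± 0.95), which led the monocyte-derived cluster, and the complement genes C3 (3.86 ± 0.83) and Cfp (3.95 ± 0.82) were higher in the monocyte lineage, and C1qc was lower (-3.64 ± 1.01). In all 173 genes were higher and 197 lower of 4498, with the library as a block and 1 residual degree of freedom. No gene passed without that block, and no list kept its call with an estimated correlation (0.704 for both lists above).

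Monocyte-lineage-like cells of Men and PV at onset and peak (7 against 4 libraries) gave no gene past the threshold of edgeR among 4775, with 191 at an unadjusted p under 0.05 and 1 by DESeq2. Simulated data of this design gave back 80 of 100 genes changed 8-fold and 8 of 100 changed 2-fold. On the PV side, PV_peak_3 and PV_peak_4 stood apart with 0% microglia-like cells, here and in the comparison with CP below. Disease-associated microglia genes had a median of -0.50 in Men relative to PV, with an adjusted camera p of 5.09e-09 that became 0.404 with an estimated correlation. CP_peak_4, the only CP library with enough such cells, stood apart, with few border-macrophage-like cells and the well pattern of another compartment. It gave 0 genes past the threshold against 3 PV peak libraries among 7015, with 523 at an unadjusted p under 0.05 and 0 by DESeq2. Without PV_peak_2 this count was 546 and without PV_peak_3 it was 9. A fit with the title number as a block, a possible pairing of preparations, gave 116 genes for CP against PV and no value for Men against PV.

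The fifth question was which compartment gained monocyte-lineage cells and when. In PV they made up 36.4 ± 26.99% of kept cells at peak (SD, n = 4) and 7.43 ± 7.42% in naive mice (n = 4), a difference of 28.98 percentage points. Of the peak libraries, PV_peak_1, PV_peak_3 and PV_peak_4 stood apart from their compartment label, PV_peak_3 and PV_peak_4 with 0% microglia-like cells. The exact permutation p was 0.0571, where 0.0286 is the smallest the design allows, and the difference was 18.8 without PV_peak_4. In Men at onset they made up 29.1 ± 14.4% (n = 7) against 8.91 ± 5.99% (n = 3), a difference of 20.2 with an exact p of 0.0833. The differences at PV onset, Men peak, CP onset and CP peak were 0.58, 2.95, 2.24 and 9.12 percentage points, with exact p values of 0.943, 0.8, 0.7 and 0.533. Before onset, CP day 8 differed by 24.1 (1.41 to 40.5% in 3 libraries against 0, exact p 0.2, highest in CP_day8_2 and CP_day8_3, which stood apart), Men day 8 by 10.3 (exact p 0.5), Men day 4 by -8.91, PV day 4 by -2.43 and PV day 8 by -4.65. None of the 120 share tests passed after adjustment, with 0.98 as the smallest adjusted p. The class make-up differed between blocks of wells in 32 of 53 libraries tested, so the shares were not independent of the position in the plate. At PV onset the value rests on PV_onset_6 (31.7%, others at most 8.47%) and is -4.16 without it. At Men peak it is -3.06 without Men_peak_1 and -0.28 without Men_naive_1. CP onset is 0.66 without CP_onset_1 and CP peak 2.64 without CP_peak_4.

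Blood monocytes were sorted as Ly6Chigh and Ly6Clow cells and fell into a classical-like and a nonclassical-like class. Classical-like cells made up 41.7% of the naive library (95% Clopper-Pearson interval 31.7 to 52.2), 50.3% at day 4 (42.4 to 58.2) and 47.4% at onset (39.4 to 55.6). Since both kinds were sorted by gate, these shares may follow the wells given to each gate and do not measure the make-up of blood. The intervals cover counting error alone. In naive blood, 38 classical-like cells lay in the lower-numbered wells and 2 in the higher-numbered ones, against 5 and 43 for nonclassical-like cells. These numbers were 62 and 20 against 11 and 46 at day 4, and 38 and 36 against 43 and 39 at onset, where the classes were not separated by well. Marker levels separated the classes at each stage: Ly6c2 was at 4964, 2408 and 4551 CPM in classical-like cells at naive, day 4 and onset and at 105.7, 150 and 395 CPM in nonclassical-like cells. Ace was at 67.5, 41.5 and 72.6 CPM against 1215, 960 and 1604 CPM, and Nr4a1, a transcription factor of nonclassical monocytes, at 284, 157 and 100.9 CPM against 1074, 1035 and 997 CPM. All 3 genes are listed class markers, so their direction follows from the naming.

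Among genes with enough transcripts, those with the largest differences from the naive library are given here for each class. In classical-like blood cells at day 4 these were all higher. S100a8 was at 3558 CPM (exact Poisson 95% interval 3399 to 3722) against 0, at least 176-fold higher, S100a9 at 2105 against 6.75 CPM, Saa3 at 1628 against 13.5 CPM and Lcn2 at 973 against 0 CPM. The same library held 5 neutrophil-like cells and the 16 unnamed cells with Saa3 among their leading genes, and neither kind of cell was found in the other blood libraries. At onset Lrg1 was at 232 against 20.3 CPM, Vcan at 516 against 67.5 CPM and Ms4a6d at 940 against 209 CPM. In nonclassical-like cells the largest differences at day 4 were lower levels, with Cd74 at 352 against 2827 CPM, H2-Aa at 270 against 2528 CPM and H2-Ab1 at 232 against 1488 CPM, and at onset H2-Aa was at 517 CPM. The naive library also held 8 cDC2-like cells, against 2 at day 4 and 0 at onset, and transcripts from such cells were not tested. Among the 10 largest differences of nonclassical-like cells at onset, Hba-a1 and Hbb-bs of erythrocytes came first and were lower, and the higher ones included Ly6a at 1340 against 105.7 CPM, Stat1 at 1044 against 299 CPM, Irf1 at 513 against 132.1 CPM and Fcgr4 at 2375 against 511 CPM. With 1 library per stage these are values without a test, and the naive and day 4 libraries were of another spike-in batch than the onset library.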

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

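The tests of the libraries standing apart and the test of library batches in CP were chosen after the result was seen. The 18 values given next each lay far from the others of their group (Dixon's ratio at its 95% critical value), among 58 groups and measures tested. Chance marks about 1 in 20 only where values are normally distributed. Where all other libraries are at 0, any value above 0 is marked, and some of these rest on 1 or 2 cells.

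In PV, the median depth of PV_naive_4 was 2475 transcripts per kept cell (others 3322 to 3425), and T cell-like cells made up 27.9% of PV_naive_1 (others at most 0.73%). Border-macrophage-like cells made up 81.2% of PV_day8_1 (others at most 6.74%) and 18.4% of PV_onset_1 (others at most 5%), and cDC2-like cells 2.35% of PV_day8_1 (others 0). PV_day8_3 held 57.3% neutrophil-like cells (others at most 4.17%) and 1.12% nonclassical-monocyte-like cells (others 0). PV_onset_1 and PV_peak_2 held 10.5% and 21.9% neutrophil-like cells (others at most 0.61% and 5.71%). PV_onset_6 held 31.7% monocyte-lineage-like cells (others at most 8.47%) and 33.5% T cell-like cells (others at most 7.89%).

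In Men, microglia-like cells made up 73.8% of Men_onset_3 (others at most 11.1%), border-macrophage-like cells 59.5% of Men_onset_4 (others at most 8.57%) and T cell-like cells 37.6% of Men_onset_7 (others at most 13.8%). In CP, CP_peak_4 held 14.3% neutrophil-like cells (others at most 1.11%), 6.35% nonclassical-monocyte-like cells (others 0) and 1.59% T cell-like cells (others 0), and CP_peak_1 held 3.23% cDC2-like cells (others 0).

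A test of the difference itself marked 3 results: the change of border-macrophage-like cells from naive differed between Men and CP for 51 genes at onset (Socs3, Dusp1 and Fos among them) and 14 at peak, and the change to peak differed between microglia-like cells of PV and border-macrophage-like cells of Men for 2 genes, H2-Q4 and Csrnp1. The Men side of each rests on Men_onset_4 or Men_peak_3, 1 library with no spread of its own and a make-up like that of CP.

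Cells outside the comparisons were the third mark. The sort left out CD3e, Ly6G and NK1.1, yet 235 cells were T cell-like, 276 neutrophil-like and 41 NK- or ILC-like. Of 95 unnamed cells, 79 (61 in Men_naive_1 and 18 in PV_day8_3) shared Prss16, Krt18, Krt8 and Ccl25 as leading genes, and 16, in Blood_day4_1, were led by Prg4 and Alox15.

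The make-up of 15 CNS libraries stood apart from their compartment label. In 8 of them border macrophages stood out: cluster 1 of that class, led by Mrc1 and Apoe, was high in Men_peak_3, Men_onset_4, PV_peak_1 and PV_day8_1, or border-macrophage-like cells were too few in CP_peak_4, CP_onset_3, CP_day8_2 and CP_day8_3. Men_peak_1, Men_peak_2, Men_onset_3, Men_day8_3 and Men_day4_1 stood apart by microglia-like cells instead (37.3 to 86.7%). PV_peak_3 and PV_peak_4 stood apart because they held 0% of such cells. No test of a wrong label was made for the libraries that stood apart by microglia-like cells alone. Of the 8, the 4 Men and PV libraries left the middle block of 64 wells empty and the 4 CP libraries filled it. Of the 6 other later CP libraries, 5 left it empty. An empty block is thus usual in later CP libraries only once the 4 CP libraries in question are set aside. A mixture of samples would fill that block, yet it was empty in all 4 of the Men and PV libraries and in 3 of 20 others (Fisher exact p 0.00329), so a wrong compartment label is a candidate explanation. Sort gates that differ between blocks of wells stay open, since the make-up differed between blocks in 10 of the 14 such libraries tested, and no biological explanation was tested.

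In microglia-like cells of PV at onset, 901 genes passed, Gbp2 and Zbp1 among them. Only 1 of 84 splits of the libraries, the real one, gave as many, and the highest other split gave 56. This makes chance unlikely as far as the libraries are independent, which the labels do not tell. Before onset, these genes differed between spike-in batches by a median of 0.0746 of their onset change, which argues against library batches as the whole cause. The 10 most abundant monocyte-lineage markers set how much monocyte-lineage RNA the sums could hold. Ly6c2, Plac8, Chil3 and Ccr2 were lower at onset than in naive mice and under 1% of their monocyte-lineage level. Fn1, Saa3 and Ms4a4c were higher, at 16.4, 25.9 and 8.19% of it. By the median of the 10, such RNA accounts for 0.0149 of the rise, as a median over genes that rose. The markers come from the lists that named the clusters, so low levels in microglia-like cells follow in part from the naming. The test can therefore not decide whether monocyte-lineage cells were assigned to this class. A response to disease stays open beside such cells and a difference in cell or RNA quality. Quality was not tested although the mitochondrial share was higher in all onset libraries.

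In border-macrophage-like cells of CP, genes such as Caps2, Usp29 and Lars2 were lower at onset and peak. In microglia-like cells of PV before onset, the same genes were lower in the batch with spike-in features by 0.317 of their fall in CP, with Lars2 at -3.65. Of 100 such genes with enough transcripts there, 91 were lower in that batch, 39 of them by 1 or more on the log2 scale. Their median difference was -0.84, against -0.107 over all genes tested in those cells. The spike-in batch cannot be told apart from the stage in CP, since both naive CP libraries are of the batch without listed features. RNA from choroid plexus epithelium also stays open: Ttr and Enpp2, the markers tested, had a median log2 change of -1.25 at onset and 0.198 at peak. Cell quality, untested, and a change of the cells with disease stay open as well. Kcnq1ot1, a usual sign of low quality, was also lower (-2.25 and -2.13). Gm10800 held 36.1 to 36.3% of transcripts in naive CP libraries, 13.1 to 24.1% at onset and 0.178 to 28.9% at peak. Median depth per kept cell averaged 2570, 4438 and 4306 transcripts in these groups.

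For 3 other comparisons the libraries were also split at random. Between Men and CP, 43 genes passed in border-macrophage-like cells. Of 100 splits run, from 216 in all, 2 gave as many, the real one included, with 44 in the highest other. Chance is therefore unlikely for the count but not excluded, and Men_onset_4 and Men_peak_3, on the Men side, stood apart. For microglia-like cells at day 8, 10 splits are too few for a share under 0.05 (0 genes in the real split, 3 in the highest other). For monocyte-lineage-like cells of Men and PV, all 60 splits gave at least the real count of 0, as any split must, so the count of splits says nothing. The highest other, with 130 genes against a median of 0, exchanges Men_peak_2 and PV_peak_2. Men_peak_2 stood apart, with 56.2% microglia-like cells, and what sets this split off was not tested.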

How the results depend on the processing

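The settings that keep Gm features, use the first naming definition, use 5 cells per library, undo the collision correction, leave out libraries standing apart, use the spike-in batch or its libraries alone, or fit all CNS libraries together were chosen after the data were examined. The number of libraries and cells limits most counts: 1 library stood on 1 side in 3 Men comparisons, CP day 8 and PV day 4 against naive, and in simulated data 0 to 13 of 100 2-fold changes were found in each design but Men against CP (41). Of 7311 values of named genes under alternatives, 5897 kept their direction and side of the threshold, 1405 were no longer past it and 9 took the other direction, and leaving out 1 library ended 320 of these calls. Unless stated, the cause of a change was not tested. A setting with fewer libraries or cells has less power by construction.

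The named values that took the other direction were Lpl in PV microglia-like cells at onset (0.049, only spike-in libraries), Fosb in CP at day 4 (-0.37, first naming definition), Cxcl1, Acp5, Cxcl2 and Tnf in CP at peak (1.82, 1.09, 0.40 and 0.35 without CP_naive_1, as low as -8.86, -5.30, -3.04 and -3.68 without CP_peak_3, CP_peak_2, CP_naive_2 and CP_naive_2), and Klf4, Fos and Cxcl2 between Men and CP (-0.36, -0.19 and -0.17, first naming definition).

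For microglia-like cells of PV, the day 4 count of 0 was 1 with DESeq2, 13 with no filter on low counts and 5 with only the 2 groups. Day 8 gave 24 with no filter and 1 in spike-in libraries. Leaving out single libraries kept 0 at both. At onset (901) the count was 489 without the C and EAE libraries, 127 with the batch covariate, 8 in spike-in libraries, 250 with all CNS libraries and 343 (without PV_naive_3) to 947 (without PV_onset_1) leaving out 1 library. The covariate left the median size of the change at 1.55 (1.57 without) and raised the median SE from 0.402 to 0.564, which ended calls. The peak count of 1 was 31 with no filter, 2 with only the 2 groups, 3 with Gm features, 2 with the first definition, 0 with the batch covariate, 3 with all CNS libraries and 0 to 1 leaving out 1 library.

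For border-macrophage-like cells of Men at day 4, onset and peak (11, 127 and 144), DESeq2 gave 0, 31 and 34, cells with 500 transcripts 0, 0 and 0, cells with 2000 transcripts 0, 27 and 16, clusters without response genes 0, 55 and 50, libraries summed by title prefix 0, 76 and 86, and 5 cells per library 0, 4 and 2. Day 4 gave 6 with no filter and 3 with all CNS libraries, and onset 222 with Gm features.

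For CP at day 4, day 8, onset and peak (11, 46, 59 higher with 69 lower, and 34 higher with 87 lower), no filter gave 30, 82, 231 and 198, Gm features 21, 130, 202 and 192, and cells with 2000 transcripts 2, 30, 69 and 76. DESeq2 gave 29, 69 and 78 from day 8 on. With only the 2 groups the counts were 0 at day 4, 84 at day 8 and 59 at peak, and with all CNS libraries 3 at day 4 and 24 at day 8. Leaving out 1 library gave 3 to 13, 15 to 38, 59 to 87 and 44 to 136, lowest without CP_day4_1 or CP_naive_1 at day 4 and without CP_naive_1 later.

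Men against CP (43) gave 24 with 2000 transcripts, 67 with Gm features, 108 with 5 cells, 7 with the first definition (which keeps 2 Men and 5 CP libraries), 98 without libraries standing apart, 8 in spike-in libraries and 23 (without Men_day4_2) to 66 (without Men_peak_3). The onset response (51) gave 95 with no filter, 4 and 22 with 500 and 2000 transcripts, 27 without C and EAE libraries, 12 with 5 cells, 29 with the batch covariate and 16 (without CP_onset_2) to 59 (without CP_naive_1). The peak response (14) gave 26 with DESeq2, 54 with no filter, 0 and 5 with 500 and 2000 transcripts, 26 without the top 2 percent of cells, 8 with Gm features, 0 with 5 cells and 1 (without CP_naive_2) to 41 (without CP_peak_3). Between PV microglia and Men border macrophages (2), DESeq2 gave 19, relative log expression factors 6, no filter 60, 500 and 2000 transcripts 0 and 0, no response genes 1, doubled resolution 9, no top 2 percent of cells 13, title-prefix sums 29, no C or EAE libraries 1, 5 cells 0, the batch covariate 4, spike-in libraries 0, and leaving out 1 library 0 (without Men_naive_2) to 4 (without PV_peak_1).

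Monocyte lineage against microglia (370) gave 201 with DESeq2, 193 with doubled resolution, 232 without the top 2 percent of cells, 244 with Gm features and 0 with no block. Men against PV (0) gave 1 with DESeq2, 19 with no filter, 6 with 20 cells, 1 with title-prefix sums, 1 without libraries standing apart and 0 leaving out any 1 library. CP against PV (0) gave 58 with no filter, 116 with a block and 0 to 546 (without PV_peak_2).

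The share difference of the monocyte lineage at PV onset (0.58) took the other sign with 500 transcripts (-0.27), no response genes (-0.51), doubled resolution (-2.96) and no C or EAE libraries (-0.75), and ran from -4.16 (without PV_onset_6) to 3.98 (without PV_naive_1). At Men peak (2.95) it was -0.22 and -2.17 with 500 and 2000 transcripts, -0.28 without C or EAE libraries and -3.06 (without Men_peak_1) to 8.40 (without Men_peak_3). PV peak, Men onset, CP onset and CP peak stayed higher, with 18.8 to 38.5, 16.9 to 23.4, 0.66 to 3.36 and 2.64 to 12.2 leaving out 1 library. The classical-like share of naive blood (41.7%) was 55.1% with 2000 transcripts.

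Of 14 gene lists, those past the threshold with an estimated correlation and with fry were 0 and 0 in microglia at day 4, day 8 and peak (3, 4 and 4 with the preset correlation) and 4 and 8 at onset (11). They were 0 and 0 in CP at day 4, day 8 and onset (5, 3 and 9), 0 and 2 at CP peak (7), 0 and 0 in Men at day 4 and onset (4 and 7), and 0 and 3 at Men peak (10). They were 2 and 2 between Men and CP (5) and in both responses (8 and 6), 1 and 0 for PV microglia against Men (10), 0 and 1 for monocyte lineage against microglia (7), and 0 and 0 for Men against PV and CP against PV (3 and 7).

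No value could be had for Men at day 8 except with 5 cells (0). The fit of all CNS libraries gives the same stage count for Men and CP, and its 24 at day 8 rests on CP_day8_1 and PV_day8_1 alone. None could be had where a setting left out the only library of an arm or every residual degree of freedom: in Men against naive, without any 1 of its libraries, without C and EAE libraries, with the first definition, without libraries standing apart (onset and peak), with the batch covariate or in spike-in libraries; in CP from day 8 on with the batch covariate and at any stage in spike-in libraries; without PV_day4_2 or in spike-in libraries at PV day 4; and without CP_day8_1. The same held for the 3 response differences without the Men library, with the first definition or without libraries standing apart, and for both responses of Men against CP in spike-in libraries. A block gave none for Men against CP or Men against PV. Monocyte lineage against microglia gave none with 20 cells, without C and EAE libraries, without either library, with the first definition or with the batch covariate. CP against PV gave none with 20 cells, without CP_peak_4, without libraries standing apart or with the batch covariate, nor did Men against PV with that covariate, or the Men peak share without libraries standing apart.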

Other observations

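No test in this part was added to those above, and the values below were looked at after the classes were named. Both libraries titled C or EAE in PV held many T cell-like cells: 38 of 136 kept cells in PV_naive_1 and 55 of 164 in PV_onset_6. In 32 wells the cell was T cell-like in both libraries. All 38 in PV_naive_1 and 53 of the 55 in PV_onset_6 lay in the last block of 64 wells, where 48 wells were kept in both.

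The border macrophage clusters held different shares of their class at the stages in CP. The cluster led by Mrc1, Apoe and Cd163 held 0% of naive border-macrophage-like cells, 18.6% at day 4, 60.7% at day 8, 66.4% at onset and 69.4% at peak, and the cluster led by Pf4, with Cbr2, RP23-341H2.4 and Kcnq1ot1, a usual sign of low-quality cells, also among its leading genes, held 94.5%, 67.4%, 33.9%, 18.1% and 23.8%. In Men, the cluster led by Cxcl2, Fos and Egr1 held 75.4% of naive, 18.8% of onset and 16.5% of peak border-macrophage-like cells. These shares of clusters were not tested and pool the cells of all libraries of a group. In CP, the naive and day 4 libraries were of the batch without listed spike-in features and all later ones of the other. Batch and stage can therefore not be told apart there from day 8 on. Depth of cells relative to their own library was 0.621 in the cluster led by Pf4 and 1.13 in the one led by Mrc1. In Men, border-macrophage-like cells were most frequent in Men_onset_4 at onset (59.5%) and in Men_peak_3 at peak (85.6%). Both stood apart, so the lower shares may not be a change in Men.

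Spike-in features were listed in 39 of the 55 libraries and in no naive, day 4 or blood library other than those of PV_naive_1, Men_naive_1 and Blood_onset_1.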
